A study of Rattus norvegicus with 15 samples.

How the data were processed

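Total RNA of epididymal fat from 7 diet-induced obese and 8 lean male Long-Evans rats was hybridised to Affymetrix RAE230_2 arrays, 1 per rat, per the labels. The labels and the series' design text disagree on the RNA input (6 and 5 micrograms) and on the reagent used to extract the RNA, and both are given here as stated. Shipping took place when the rats were 14 weeks old; after 2 weeks to settle they had a glucose test at week 21 of life, a fasted blood sample at week 25 and were killed at week 26. The numbers in the titles name different rats in each group, and no obese rat 4 was analysed here.

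The deposited values are intensity values, on a linear scale: MAS5 signals, per the submitters' processing notes, with the version and the background settings not given in the sources used here. Detection calls were not used here. The table held 31099 probe sets, of which 57 were controls. The deposited intensity values had a 2% trimmed mean of about 1500.4 on every array, so they were taken as scaled by the authors and used as deposited. MAS5 subtracts mismatch signal, which makes low signals noisy, and its scaling to a common mean lets a few bright probe sets lower the rest.

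Signals were put on the scale log2(signal + 79.9), where 79.9 is the 10th percentile of all signals. Fold changes are on that scale, which understates the change of dim genes. Probe sets with a mean log2 value above the 40th percentile were kept, leaving 18625 probe sets and 10514 genes. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene names came from the platform annotation: 20826 probe sets named 1 gene, 436 several and 9780 none, and 20758 of the first matched a current Entrez ID. No gene was named from a probe set with several. A gene's value is its brightest probe set; of 129 named genes, 22 had over 1 probe set and for 4 (Lipe, Akt1, Ciita and Pdgfrb) these differed in sign. Probe sets of close relatives such as the stearoyl-CoA desaturases can bind each other's transcripts, which was not tested.

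Gene lists were tested with camera (preset correlation 0.01, two-sided), with fry beside it; 35 lists were written and 32 held the minimum of 4 genes above the filter. Neutrophil, epididymal epithelium and red blood cell markers had 1, 1 and 3. The genes named were, by a rule fixed before the data were examined: up to 12 of the largest changes past the threshold in each direction, or, where none passed, the 5 with the smallest p in each direction; 18 fixed genes; and up to 3 members of each list with the smallest p, or 4 where members went both ways. A result on an item withheld for evaluation was left out. Applying the first part to the fit without the near-identical arrays was decided after seeing the data. Array measures were compared with exact two-sided permutation tests.

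Alternatives fixed before the data were examined were pseudocounts of 1 and 291.2, no filter and a filter at the 60th percentile, median centring, quantile normalization, the rat number as a block, array weights, eBayes with trend and robust, the Gapdh 3 prime to 5 prime ratio as a covariate, each rat left out, 1 probe set per gene, the mean over a gene's probe sets and an estimated correlation in camera. Added after seeing the data were the fit without the near-identical arrays, all of those alternatives in it, the spike-in level as a covariate and the exact permutation over list means. The filter and pseudocount stayed those of all 15 arrays.

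The limma step was tested on simulated data with the real means and residual spreads and, among 18625 probe sets, 50 changed by each of 4 sizes. For the comparison of all 15 arrays it recovered 52% of those changed by 0.5 on the log2 scale, 86% at 1, 98% at 2 and 100% at 3, and 6.15% of calls were false. For the comparison of 13 arrays it recovered 26%, 88%, 98% and 100%, with 7.14% false. The simulated noise was independent between probe sets, which that of real arrays need not be. These shares therefore show that the step works and do not give its recovery or false calls on the real arrays, where the 15-array fit passed 0. With independent genes, a list moved by 0.3 was called in both and 0 of 31 lists sharing no member with it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.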

Results

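Epididymal fat, the visceral fat depot beside the testis, was profiled in 15 male Long-Evans rats, 1 Affymetrix RAE230_2 array per rat. The diet-induced obese group held 7 rats kept since weaning on a diet rich in fat and sucrose, and the lean group held 8 rats kept on ordinary chow. All rats were killed at 26 weeks of age in the fed state. The question was which transcripts of this depot differed between obese and lean rats. Diet and obesity changed together, so the comparison cannot separate them. The values were MAS5 signals, the brightness that the Affymetrix MAS5 program gives to each probe set, a group of probes against 1 transcript. Signals, those of control probe sets included, ran from 0.4 to 511805, and every array had a trimmed mean between 1500.34 and 1500.42. The highest signal was that of a control probe set on the array of obese rat 3. The number of arrays, 7 against 8, limits the precision. The arrays of obese rat 1 and lean rat 7 were close to identical although labelled as different groups, and nothing in the labels says which group is right for either. Results are therefore given with all 15 arrays, as fixed before the data were examined, and without this pair, an alternative chosen after seeing the data that leaves 6 obese and 7 lean rats.

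Without the near-identical pair, obese fat had higher signals of Scd, Fabp3, Fabp5, 6 of 25 macrophage markers and 4 of 36 matrix genes, and lower signals of Mest, Cbr1 and Frzb; with all 15 arrays no probe set passed the threshold. Scd (Entrez gene 246074), the enzyme that puts a double bond into saturated fatty acids, rose most without the pair. Its signal was 73649.5 ± 19376.8 (SD, n = 6) in obese and 9838 ± 5812 (SD, n = 7) in lean rats, a log2 fold change of 3.06 ± 0.34 (SE; limma adjusted p = 0.00257). All 6 obese rats lay above all 7 lean rats, which 1 of 1716 regroupings would give. Scd was among the genes fixed beforehand, but the pair was left out after seeing the data. With all 15 arrays the log2 fold change of Scd was 2.60 ± 0.50 (SE; limma adjusted p = 0.0948). The groups then overlapped: obese rat 1, at 12.65 on the log2 scale, lay within the lean range of 11.81 to 14.30.

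Of 18625 probe sets tested with all 15 arrays, limma passed 0 at an adjusted p of 0.05, while 2898 had an unadjusted p under 0.05, against 931 expected by chance. Without the pair 189 passed, 135 higher and 54 lower in obese rats, and 47 of them had a log2 fold change of at least 1 in size. By 1 probe set per gene they named 116 genes, 91 higher and 25 lower. All 189 moved the same way with 15 arrays, where their highest adjusted p was 0.198. Leaving out obese rat 1 alone gave 245 and leaving out lean rat 7 alone gave 1. From the 189, leaving out 1 more rat gave 111 without obese rat 5, 61 without obese rat 6, 54 without obese rat 7, 52 without obese rat 8, 94 without lean rat 2, 99 without lean rat 3, 74 without lean rat 4, 51 without lean rat 5 and 54 without lean rat 6. The count was 163 without obese rat 2, 262 without obese rat 3, 151 without lean rat 1 and 134 without lean rat 8. The log2 ratio of 3 prime to 5 prime signal of Gapdh, which grows as RNA degrades, was 0.72 ± 0.28 (SD, n = 6) in these obese and 1.05 ± 0.28 (SD, n = 7) in these lean rats (exact two-sided permutation p = 0.0589, adjusted p = 0.0706), and with that ratio as a covariate 14 probe sets passed. Centring each array on its median moved the median log2 fold change of all probe sets from -0.04 to 0.07, and relative to it 389 passed, 357 higher and 32 lower.

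**Figure D1:**
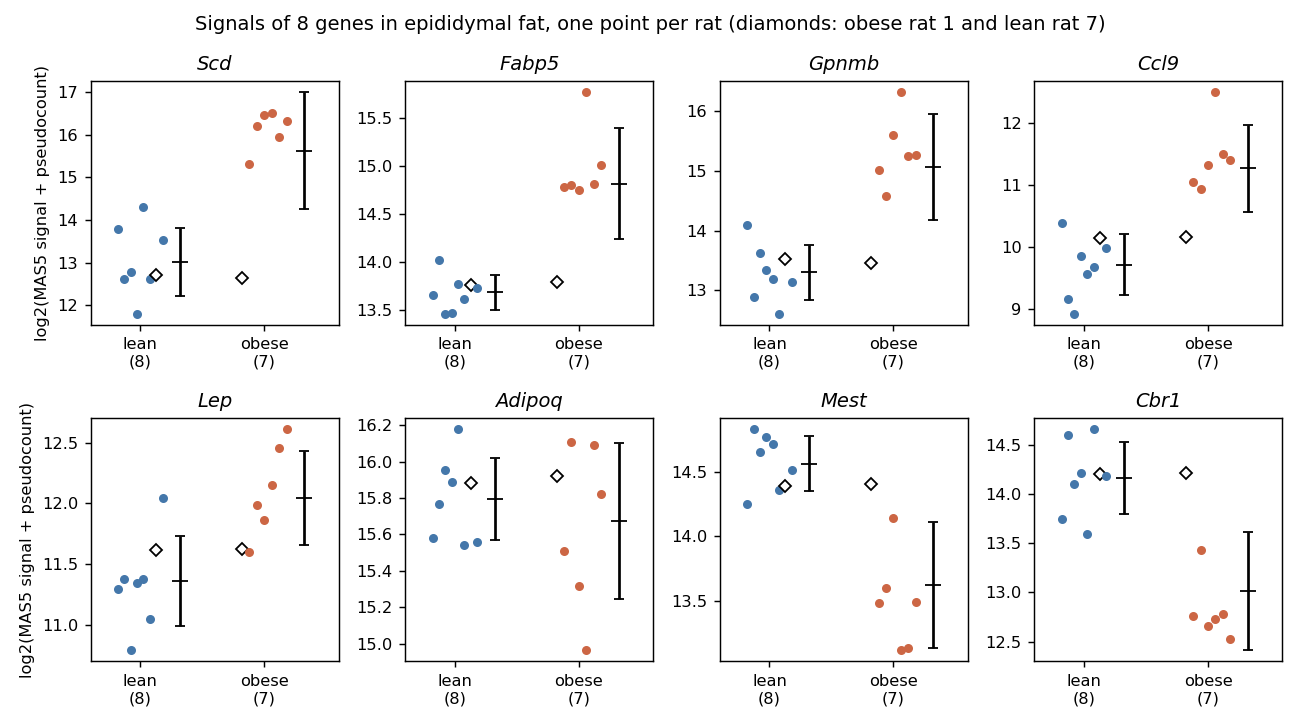
Each point is 1 rat; the y axis is log2(MAS5 signal + pseudocount), and the bars are the mean ± SD over all 8 lean or 7 obese rats. Open diamonds are obese rat 1 and lean rat 7, which lie close together in every panel; for Scd they are at 12.65 and 12.72, while the other 6 obese rats lie between 15.32 and 16.50.

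The 12 genes with the largest increases without the pair were Scd and the 11 that follow. Fabp3 (Entrez gene 79131) and Fabp5 (140868), which carry fatty acids inside the cell, had log2 fold changes of 2.38 ± 0.41 and 1.31 ± 0.16 (SE; limma adjusted p = 0.0181 and 0.00326). Gpnmb (113955), a membrane glycoprotein made by macrophages, rose by 2.07 ± 0.26, from a lean signal of 10308 ± 3693 (SD, n = 7) to 44416 ± 19909 (SD, n = 6; limma adjusted p = 0.00326). The chemokine Ccl9 (360579) rose by 1.79 ± 0.26 (SE; limma adjusted p = 0.00874). Spp1 (osteopontin), Cd5l, a protein secreted by macrophages, Itgax (CD11c), an integrin of dendritic cells and macrophages, and the nuclease Dnase1l3 had log2 fold changes of 1.77, 1.72, 1.38 and 1.34. The keratin Krt79, the phosphodiesterase Pde8a and the carboxypeptidase Cpa1 had 1.78, 1.72 and 1.52. The limma adjusted p of these 7 genes ran from 0.0249 for Dnase1l3 to 0.0453 for Pde8a. With all 15 arrays the log2 fold changes of the 12 genes ran from 1.13 for Fabp5 to 2.60 for Scd, and none passed.

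The decreases were smaller. Without the pair, Slc22a3 (29504), an organic cation transporter, had a log2 fold change of -1.50 ± 0.25 (SE; limma adjusted p = 0.0157) and a signal of 470 ± 215 (SD, n = 6) in obese against 1438 ± 520 (SD, n = 7) in lean rats. Carbonyl reductase Cbr1 (29224) had -1.34 ± 0.19, the secreted Wnt antagonist Frzb (295691) -1.16 ± 0.15 and Mest (58827), an imprinted gene linked to fat cell growth, -1.10 ± 0.16 (SE; limma adjusted p = 0.00655, 0.00326 and 0.00961). Ankef1 had -1.03 ± 0.13 (SE; limma adjusted p = 0.00326). Ppp1r13l, Cntnap2, Calb2, clusterin (Clu), Fmr1, Mamdc2 and the complement regulator Cd55 had log2 fold changes from -1.44 for Ppp1r13l to -0.69 for Cd55, with limma adjusted p from 0.0234 to 0.0467. The mean over a gene's probe sets gave Clu -1.33 and Cd55 -0.39 (limma adjusted p = 0.0183 and 0.126). With all 15 arrays, the genes with the smallest p, each at an adjusted p of 0.0948 and so short of the threshold, were Fabp5, Ccl9, Gpnmb, the kinase Fam20c at 1.07 and the protease inhibitor Lxn at 0.66, and among lower genes Mest at -0.94, Cbr1 at -1.15, Zfp275 at -0.47, Cd55 at -0.60 and Sepsecs at -0.46. Of 46 named genes that passed without the pair, 15 passed in every fit that left out 1 more rat. Of the 46, Scd alone passed in every fit without the pair, with log2 fold changes from 2.70 to 3.26.

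Among genes fixed for their part in fat biology, Scd, Mest and Cd68 passed without the pair. Leptin (Lep, 25608), the fat cell's hormone of stored energy, had a signal of 4476 ± 1189 (SD, n = 6) in obese and 2569 ± 772 (SD, n = 7) in lean rats, a log2 fold change of 0.79 ± 0.19 (SE; limma adjusted p = 0.0646). With all 15 arrays Lep had 0.68 ± 0.18 (SE; limma adjusted p = 0.115), and it missed the threshold in both; over the alternatives without the pair its adjusted p ran from 0.0324 to 0.268. The macrophage marker Cd68 rose by 1.03 ± 0.22 without the pair (SE; limma adjusted p = 0.0399). There adiponectin (Adipoq) had a log2 fold change of -0.15 ± 0.18, the fat cell regulator Pparg 0.06 ± 0.14, the insulin-sensitive glucose transporter Slc2a4 -0.20 ± 0.14, fatty acid synthase (Fasn) 0.14 ± 0.12 and Pck1 0.26 ± 0.17 (SE). The lipases Lpl and Lipe had -0.24 ± 0.24 and 0.01 ± 0.15, Ppargc1a -0.38 ± 0.27, Sfrp5 -0.08 ± 0.29, the chemokine Ccl2 0.19 ± 0.28 and Hsd11b1, which makes active glucocorticoid, -0.22 ± 0.23 (SE). The limma adjusted p of these 11 genes ran from 0.452 to 0.985, and quantile normalization turned the sign of Pparg, Lipe and Sfrp5, median centring that of Sfrp5, and the Gapdh ratio as a covariate that of Lpl, to 0.17, and Ccl2, to -0.25. Tnf lay below the filter on low signals, and no probe set named Retn as its single gene.

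**Figure D2:**
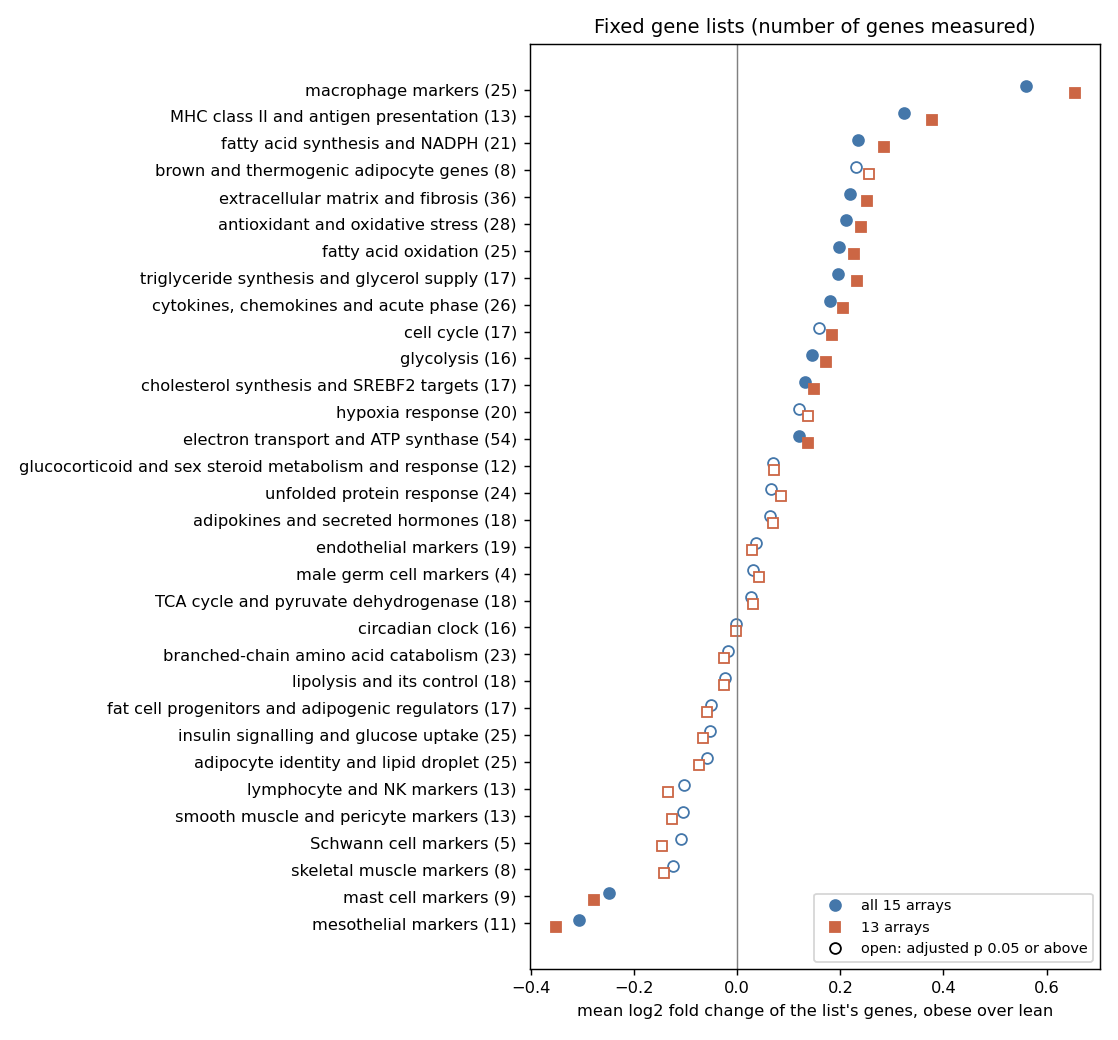
Each line is 1 of the 32 fixed gene lists, with its number of measured genes; the x axis is the mean log2 fold change of its genes, obese over lean, with all 15 arrays (circles) and without the pair (squares), and filled points have a camera adjusted p under 0.05. Macrophage markers lie farthest to the right, at 0.56 and 0.65, and mesothelial markers farthest to the left, at -0.31 and -0.35.

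Macrophage markers were higher as a list. All 25 measured members had positive log2 fold changes, with a median of 0.48 over 15 arrays (camera adjusted p = 4.87e-15; adjusted p = 0.25 with an estimated correlation; exact two-sided permutation p = 0.0028, adjusted p = 0.0224). Without the pair the median was 0.55 (camera adjusted p = 3.81e-16; adjusted p = 0.173 with an estimated correlation), and 6 members rose over all probe sets and 18 when adjusted over the list alone. With 15 arrays these counts were 0 and 15. Each rat's mean over the list, relative to all 15 arrays, was highest in obese rat 6, at 1.06. It was -0.06 in obese rat 3 and -0.24 in obese rat 1, within the lean range of -0.60 to 0.08. Beside Gpnmb and Cd68, the lectin Lgals3 rose by 0.90 and the lysosomal membrane protein Laptm5 by 0.97 without the pair (limma adjusted p = 0.0199 and 0.0273). MHC class II and antigen presentation genes had 11 of 13 members positive and a median of 0.35 over 15 arrays (camera adjusted p = 9.22e-05; adjusted p = 0.286 with an estimated correlation). Obese rat 6 had a mean of 0.79 over that list, against -0.10 to 0.17 in the other obese rats and -0.37 to 0.08 in lean rats. In that list Itgax passed without the pair, while Ifi30 at 0.59, RT1-DMa at 0.41 and the regulator Ciita at -0.38 did not. Cytokines, chemokines and acute phase genes had a median of 0.11 over 26 members (camera adjusted p = 0.0306; adjusted p = 0.25 with an estimated correlation). Their call held in 21 of 30 alternatives. Among others, it was lost with the Gapdh ratio as a covariate (adjusted p = 0.29, within a range of 0.0118 to 0.29 over the alternatives). It was also lost when obese rat 2 or 8 or lean rat 6 or 7 was left out (adjusted p from 0.0606 to 0.113). Spp1 and Mif rose in it without the pair, Mif by 0.91, and Nfkbia at 0.59 and Cxcl10 at -0.47 did not pass.

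Among lists of lipid and energy metabolism, 6 were called higher by camera with 15 arrays, and antioxidant genes are given with them. Fatty acid oxidation genes had 21 of 25 members positive and a median of 0.16 with 15 arrays (camera adjusted p = 6.96e-06; adjusted p = 0.107 with an estimated correlation). Without the pair Pdk4, the kinase that turns off pyruvate dehydrogenase, rose by 1.03 ± 0.18 and the thiolase Acaa2 by 0.60 ± 0.13 (SE; limma adjusted p = 0.0203 and 0.0473), and the other 23 members did not pass. The mean over its probe sets gave Pdk4 0.60 (limma adjusted p = 0.0453). Fatty acid synthesis and NADPH genes had 13 of 21 members positive and a median of 0.08 (camera adjusted p = 0.00294; adjusted p = 0.25 with an estimated correlation); without the pair Scd, transketolase (Tkt) at 0.50 and the citrate carrier Slc25a1 at 0.44 rose and 18 did not pass. Triglyceride synthesis genes had a median of 0.12 over 17 members (camera adjusted p = 0.00432; adjusted p = 0.25 with an estimated correlation), with Fabp5 and the fatty acid transporter Slc27a1, at 0.55, passing without the pair. Glycolysis genes had a median of 0.12 over 16 members (camera adjusted p = 0.00294; adjusted p = 0.25 with an estimated correlation), with Pfkfb3 at 0.63 and Eno1 at 0.48 passing without the pair. Electron transport and ATP synthase genes had 48 of 54 members positive and a median of 0.10 (camera adjusted p = 1.04e-05; adjusted p = 0.434 with an estimated correlation). No member passed, and quantile normalization ended the call, at a median of 0.02 and an adjusted p of 0.173, within a range of 1.56e-07 to 0.434 over the alternatives. Cholesterol synthesis genes had a median of 0.13 over 17 members (camera adjusted p = 0.037; adjusted p = 0.286 with an estimated correlation); no member passed, and the call was lost when obese rat 1, 2, 3 or 6 or lean rat 1, 4 or 6 was left out (adjusted p from 0.0554 to 0.1). It was also lost with the Gapdh ratio (adjusted p = 0.113), with array weights (0.0981) and with the replicate block (0.0565). Antioxidant genes had a median of 0.20 over 28 members (camera adjusted p = 1.03e-05; adjusted p = 0.107 with an estimated correlation), and without the pair the peroxiredoxins Prdx6 and Prdx5 rose by 0.51 each.

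Matrix genes were higher as a list, and markers of mast cells and of mesothelium, the lining of the fat pad, were lower. Extracellular matrix genes had 28 of 36 members positive and a median of 0.16 with 15 arrays (camera adjusted p = 6.96e-06; adjusted p = 0.25 with an estimated correlation). Without the pair 4 members rose, among them Timp1 by 1.26 ± 0.20 and the collagens Col1a1 by 0.82 ± 0.16 and Col6a2 by 0.87 ± 0.18 (SE; limma adjusted p = 0.0125, 0.0305 and 0.0399). With the Gapdh ratio as a covariate Col6a2 had 0.58 (limma adjusted p = 0.183). Mast cell markers had 0 of 9 members positive and a median of -0.21 (camera adjusted p = 0.0143; adjusted p = 0.25 with an estimated correlation). Their call held in 25 of 30 alternatives. Among those that ended it, quantile normalization gave an adjusted p of 0.0804, within a range of 0.00346 to 0.25 over the alternatives. Mesothelial markers had a median of -0.32 over 11 members (camera adjusted p = 0.00848; adjusted p = 0.527 with an estimated correlation). With the Gapdh ratio as a covariate their median was -0.12 (adjusted p = 0.165, within a range of 4.78e-05 to 0.527). No member of the mast cell or mesothelial list passed. Cell cycle genes were called without the pair alone, with a median of 0.16 over 17 members (camera adjusted p = 0.0389; adjusted p = 0.198 with an estimated correlation), against 0.12 with 15 arrays (camera adjusted p = 0.0718). That call was lost when obese rat 2, 5, 6 or 8 or lean rat 2 or 8 was also left out (adjusted p from 0.0521 to 0.0739). It was also lost with the filter at the 60th percentile (adjusted p = 0.606), with the Gapdh ratio (0.0699), with median centring (0.0522) and with trend and robust (0.0513).

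Of the 32 gene lists fixed before the data were examined, camera called 13 with all 15 arrays, 11 higher and 2 lower, and without the pair the same 13 and cell cycle. These calls used a preset inter-gene correlation of 0.01. With the correlation estimated for each list, 0 of the 13 held with 15 arrays, and antioxidant genes alone held without the pair (adjusted p = 0.0487 with an estimated correlation). An exact permutation of the rats over each list's mean, added after seeing the data, called 11 lists with 15 arrays and 12 without the pair. In both it did not call 4 lists that camera called: cholesterol synthesis (adjusted p = 0.0815 with 15 arrays), electron transport (0.123), mast cell markers (0.086) and mesothelial markers (0.247). In both it called brown and thermogenic genes (exact permutation adjusted p = 0.0439 with 15 arrays) and hypoxia response (0.0236), which camera did not. The brown and thermogenic mean of 0.23 rests on Fabp3, at 2.17, since 3 of its 8 members were positive. Fry, which tests whether a list's genes move one way without comparing them with other genes, called 4 and 10. Over 99 random regroupings of the 15 arrays, camera called at least 1 list in 89 and a median of 3. Adipokines, brown and thermogenic genes, endothelium and steroid metabolism had a median and a camera direction of different sign in both sets of arrays, as had hypoxia response with 15 arrays and lipolysis without the pair. Camera called none of these.

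The other 18 lists were not called by camera in either set of arrays. With 15 arrays the median log2 fold change was -0.05 for adipocyte identity, 0.02 for the TCA cycle, -0.06 for branched-chain amino acid catabolism, -0.04 for insulin signalling, 0.04 for the unfolded protein response and -0.05 for endothelial markers (camera adjusted p = 0.447 for each). It was -0.06 for adipokines, 0.00095 for lipolysis, -0.07 for the circadian clock and -0.0032 for steroid metabolism (camera adjusted p = 0.508, 0.901, 0.519 and 0.407). It was -0.04 for brown and thermogenic genes, -0.05 for fat cell progenitors and -0.0022 for hypoxia response (camera adjusted p = 0.472, 0.585 and 0.177). In these last 3 lists, Fabp3 and the lipid droplet protein Cidea, Mest, and Pfkfb3 passed without the pair, Cidea at 0.60 ± 0.11 (SE; limma adjusted p = 0.0203). In the circadian list the repressor Nr1d1 had -0.45 and Per1 1.04 without the pair (limma adjusted p = 0.116 and 0.161). Among cell types the median was -0.08 for lymphocytes, -0.02 for smooth muscle, 0.06 for male germ cells, -0.14 for skeletal muscle and -0.17 for Schwann cells (camera adjusted p = 0.0993, 0.453, 0.585, 0.21 and 0.338). Centring arrays on their median, which shifts all genes upward, made the negative medians of these lists positive except those for skeletal muscle and Schwann cells. The Schwann cell marker Gfra3 fell by 0.52 on the log2 scale without the pair (limma adjusted p = 0.0479).

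**Figure D3:**
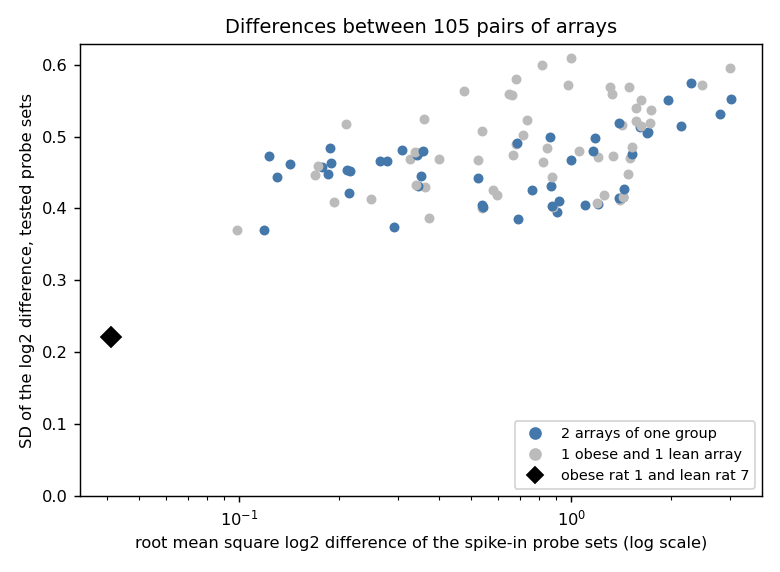
Each point is 1 pair of arrays, blue within a group and grey between groups; the x axis is the root mean square log2 difference of the 9 spike-in probe sets (log scale) and the y axis the SD of the log2 difference over the tested probe sets. The pair of obese rat 1 and lean rat 7 (black diamond), at 0.0412 and 0.221, lies apart from the other 104 pairs, whose lowest values are 0.0988 and 0.369.

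Obese rat 1 and lean rat 7 were closer to each other than any other pair of arrays. The SD of their log2 difference over the tested probe sets was 0.221, against 0.369 for the next pair and a median of 0.47 over the other 104. Their deviations from the other arrays correlated across probe sets with r = 0.707, against at most 0.374 for any other pair; probe sets are not independent replicates. The 9 spike-in probe sets, which report control transcripts added to each sample, differed between them by a root mean square of 0.0412 on the log2 scale, against 0.0988 for the next pair and a median of 0.787. Only 11 of their signals were equal to the decimal given, against up to 14 in other pairs, so the values are not a copied column.

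Of 6 array measures compared with all 15 arrays, 3 differed past the threshold after adjustment. The median signal was 748 ± 48.7 (SD, n = 7) in obese and 808 ± 38.8 (SD, n = 8) in lean arrays (exact two-sided permutation p = 0.0211, adjusted p = 0.0423). The share of signals under the pseudocount was 10.5% ± 0.947 against 9.45% ± 0.604 (SD; exact permutation p = 0.0179, adjusted p = 0.0423). The log2 ratio of 3 prime to 5 prime signal was 0.77 ± 0.28 against 1.05 ± 0.26 for Gapdh (SD; exact permutation p = 0.0746, adjusted p = 0.0895) and 1.38 ± 0.37 against 1.75 ± 0.23 for beta-actin (SD; exact permutation p = 0.0373, adjusted p = 0.0559). Trimmed means, which the scaling holds nearly fixed, differed by 0.0272 of a signal unit (exact permutation p = 0.018, adjusted p = 0.0423). The spike-in level had an exact permutation p of 0.683, and so missed the adjusted threshold, as did both 3 prime to 5 prime ratios. Obese rat 3 stood apart on the second principal component, at 51.7 against -22.8 to 9.27 for the other arrays, and had the highest spike-in level, 16.19 on the log2 scale.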

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

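The tests in this part, except the counts over other splits of all 15 rats, were chosen after the results were seen. A rat is given here where it was the highest or lowest of its group and its gap to the nearest rat, as a share of the group's range, exceeded Dixon's 95% critical value. Among 268 groups of values 22 had such a rat, against 13.4 expected from chance, which gives about 1 in 20. All values are log2(signal + pseudocount).

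Obese rat 1 accounts for 5 of the 22. It was lowest of the obese rats for Scd, at 12.65 against 15.32 to 16.50, and for Pde8a, at 9.05 against 10.89 to 11.96. It was highest for Ankef1 (12.56, next 11.47), Gfra3 (10.65, next 10.09) and Pcca (12.59, next 12.24). This rat's array is 1 of the near-identical pair. Scd, also a fixed gene, Pde8a and Ankef1 were named among the largest changes in the fit without this rat. That choice favours genes in which it departs from the other obese rats, so its count of flags is no separate evidence.

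For the near-identity of obese rat 1 and lean rat 7, different rats that happen to be alike are argued against as the whole cause by the spike-ins, which do not come from the rat: the share of pairs with a difference as small was 0.00952, that of this pair alone. The scaling of each array lets the spike-in level follow the sample's other signals, which weakens this argument. The SD of the spike-in differences, which leaves out a shift in level, was 0.0421 for this pair. It was again the smallest, against 0.0709 for the next pair. The correlation of their deviations, 0.707, restates the near-identity and is no separate test. One labelled preparation measured on both arrays remains open and is consistent with the spike-in difference of 0.0412, the smallest of all pairs. Arrays handled side by side could share part of that closeness, and close kinship was not tested. The SD of the log2 difference ran from 0.402 to 0.514 between obese rat 1 and the other obese rats. Between lean rat 7 and the other lean rats it ran from 0.369 to 0.480. These ranges overlap and do not show which array lay further from its labelled group. Leaving out obese rat 1 alone gave 245 probe sets past the threshold, against 1 for lean rat 7. If a label is wrong, these counts point to the obese one. No test of the labels was run, and both may be right.

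Other single rats are given as values. Among obese rats, Dlst was highest in rat 6 (12.995, next 12.68), as was Itgax (13.01, next 11.33). Myh1 was lowest in rat 7 (13.59, next 13.74) and Tmem151a in rat 5 (8.77, next 9.93). Among lean rats, the lowest values were Cebpd in rat 5 (10.38, next 10.97), Serpina12 in rat 5 (9.58, next 11.54), Cox5b in rat 1 (13.36, next 13.74), Pdgfrb in rat 4 (8.75, next 9.90), Ppargc1a in rat 4 (8.67, next 9.77), Pdk4 in rat 8 (9.81, next 10.42), Slc27a1 in rat 8 (11.01, next 11.35) and Sfrp5 in rat 6 (7.84, next 9.32). The highest values in lean rats were Pcna in rat 8 (12.68, next 12.26), Per2 in rat 3 (11.89, next 11.53), Zap70 in rat 3 (10.67, next 10.37), Pfkp in rat 1 (10.72, next 10.47) and Trib3 in rat 1 (10.94, next 10.55).

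Counts were compared over 100 splits of the rats, the real one included, drawn from 1716 possible without the near-identical pair and 6435 with all 15 arrays. Without the pair, 1 of the 100, the real one, gave as many as 189 probe sets past the threshold and the highest other gave 1. A random grouping of these rats is thus an unlikely source of that count. The pair was left out after seeing the data and the splits do not repeat that choice, so chance is not excluded. With all 15 arrays the real count was 0, which any split reaches (all 100 did, highest other 1), so that count decides nothing. For probe sets with an unadjusted p under 0.05, the real 2898 with 15 arrays were reached by 2 of 100 splits (highest other 3601). For lists called by camera, 2 of 100 splits gave as many as the real 13 with 15 arrays (highest other 14). Without the pair, 1 of 100 gave as many as the real 14 (highest other 13). Chance is thus unlikely for these totals but is not excluded, since other splits came close to or above them. For a single camera call these counts say less still, since 89 of the 99 other splits called at least 1. The exact permutation of the rats gave an adjusted p under 0.05 over the 32 lists for 11 lists with 15 arrays and 12 without the pair. This limits the expected share of false calls among them and does not exclude chance for each list. The lists it called include brown and thermogenic genes and hypoxia response, whose medians changed sign over the alternatives.

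For the 189 probe sets without the pair, RNA integrity, as far as the Gapdh ratio measures it, is argued against as the whole cause: with the Gapdh ratio as a covariate a median of 0.918 of the log2 fold change was kept (quartiles 0.846 and 1.04), with the sign unchanged for all 189. The 189 were picked in the same rats without the covariate, and the beta-actin ratio was not used as a covariate. Any part of RNA integrity that the Gapdh ratio misses stays open. Only 13 of them stayed past the threshold: the standard error grew by a median factor of 1.18, and over all probe sets those with an unadjusted p under 0.05 fell from 3323 to 2646, which raises the adjusted p. Which of these ended the calls was not separated. The authors' scaling as the whole cause is argued against by a median of 0.947 kept after quantile normalization (quartiles 0.881 and 1.02), where 110 stayed past the threshold. A biological difference between the diet groups remains open and untested, and a batch that followed the groups, for which the labels give no information, remains open too.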

How the results depend on the processing

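The alternatives applied without the near-identical arrays, the spike-in covariate, and the permutation over lists were chosen after seeing the data. With all 15 arrays the count of 0 held under both pseudocounts, median centring, quantile normalization, the replicate block, array weights, both covariates and 1 probe set per gene. It became 3 (0 higher, 3 lower) without a filter, 49 (34 higher, 15 lower) with the filter at the 60th percentile, which tests fewer probe sets, 8 (6 higher, 2 lower) with trend and robust, and 189 (135 higher, 54 lower) without the near-identical arrays. Leaving out 1 rat gave 0 to 245 (0 to 170 higher, 0 to 75 lower); only the fits without obese rat 1 (245) and lean rat 7 (1) were above 0.

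Without the near-identical arrays the 189 calls (135 higher, 54 lower) became 124 (83 higher, 41 lower) with a pseudocount of 1, 255 (187 higher, 68 lower) with that at the 25th percentile, 46 (30 higher, 16 lower) without a filter, 334 (234 higher, 100 lower) with the filter at the 60th percentile, 389 (357 higher, 32 lower) with median centring and 124 (89 higher, 35 lower) with quantile normalization. They became 261 (175 higher, 86 lower) with array weights, 309 (232 higher, 77 lower) with trend and robust, 281 (176 higher, 105 lower) with the spike-in covariate, 158 (121 higher, 37 lower) with 1 probe set per gene and 14 (10 higher, 4 lower) with the Gapdh ratio. Leaving out 1 further rat gave 51 to 262 (32 to 155 higher, 14 to 107 lower). The cause was not tested, except that the filters change the number of probe sets tested and fewer rats give fewer degrees of freedom. Of the 189, 165 remained with median centring and 110 with quantile normalization.

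The rat numbers did not pair the groups: the deviations of same-numbered rats correlated between -0.108 and 0.244, with 2 of 7 above 0.1, and 1 of 7 obese rats correlated best with its own number. With the replicate block, which spends degrees of freedom on the numbers, the count was 0 with 15 arrays and 3 (3 higher, 0 lower) without the pair.

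The count of lists called by camera was 13 with 15 arrays and 14 without the pair. It became 0 and 1 with an estimated correlation and 9 without the pair when the Gapdh ratio was a covariate; leaving out 1 rat gave 11 to 15 in both. No called list or named gene changed direction under the alternatives. Named genes that changed sign without the pair were Lipe, Pparg and Sfrp5 and, with the Gapdh ratio, Lpl (-0.24 to 0.17), Ccl2 (0.19 to -0.25), Egfl8 and Myl1; lists such as lipolysis did too. Limma called none of these genes and camera none of these lists. Hypoxia response and brown and thermogenic genes, which the exact permutation called, also changed the sign of their median. Of the 14 lists called without the pair, 9 were called in every fit that left out 1 further rat. The obese minus lean difference in the log2 beta-actin ratio was -0.37 with all 15 arrays (exact permutation p = 0.0373) and -0.41 without the pair (exact permutation p = 0.0501). Leaving out 1 of the 15 rats gave -0.48 to -0.31 (exact permutation p from 0.005 to 0.0749). For Gapdh, leaving out 1 of the 15 gave -0.34 to -0.21 (exact permutation p from 0.0251 to 0.159). Signals near the pseudocount of 79.9 limit what can be said of dim genes.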

Other observations

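The tests in this part were chosen after the results were seen. Lysosomal genes recurred among the higher genes without the near-identical arrays, a theme not among the fixed lists. Of 46 measured members of a list of lysosomal enzymes, membrane proteins and proton pump subunits written after those genes were seen, 39 had positive log2 fold changes and 9 passed in limma, among them the cathepsins Ctsz at 0.91 ± 0.19, Ctsd at 0.73 ± 0.15 and Ctsa at 0.72 ± 0.14, the acid lipase Lipa at 0.83 ± 0.18 and the proton pump subunit Atp6v1b2 at 0.51 ± 0.11 (SE). The hypothesis that lysosomal genes were higher as a group was examined on the 37 members that did not pass, which come from the same rats and include near misses such as Ctsk at 1.17. Their mean was higher by 0.22 on the log2 scale in obese rats without the near-identical arrays (exact permutation p = 0.000583, the smallest that 1716 regroupings can give) and by 0.18 with all 15 (exact permutation p = 0.00218). As the list was written after some of its genes were seen to be high, these values decide nothing and the hypothesis stays open. Macrophages are rich in lysosomes, so this may be the same change as that in macrophage markers, and these data do not separate them.

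For the higher macrophage markers, a lower share of fat cells is argued against as the whole cause. It would raise the markers of every other cell type alike, and they moved apart: the macrophage mean was higher by 0.65 on the log2 scale without the near-identical arrays, while the mean over 6 other non-fat cell type lists was -0.17, and the difference had an exact permutation p of 0.00233. Of the 6, mesothelial and mast cell markers were lowest, at -0.35 and -0.28, and endothelial markers were at 0.03. A lower share of fat cells beside another change is not excluded. More macrophages of an unchanged kind remains open: the shifts of the 22 markers above the median signal differed more than in regroupings of the rats (SD 0.411 against a median of 0.164; exact permutation p = 0.000583, the smallest possible), but markers that other cells also make would shift less, so this spread decides nothing. RNA integrity stays open: with the Gapdh ratio as a covariate the difference was 0.49 ± 0.19 (SE) on the log2 scale, against 0.65 ± 0.17 without it, and the bound set for this test, a difference of 0.33, lies within 1 SE of it. A change in their state was not tested.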
